A study of Glycine max with 2 samples.

How the data were processed

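Total RNA of soybean seedlings was extracted with Trizol, labelled with biotin and hybridised to Affymetrix Soybean Genome Arrays, per the labels' protocols. Seedlings grew in vermiculite with 16 h of light at 25 °C. From each time point, 0.5 µg of RNA went into a salinity pool or a mock pool, and 10 µg of total RNA is given as the amount labelled. The protocol on treatment lists times of 1, 3, 6, 12 and 24 h, and the text on the design also lists 0 h, so it is open whether the pools hold 0 h samples. The groups, salinity and mock, were taken from the labels, with 1 array each. Pooling averages over times and plants, so no time course and no spread between plants can be had.

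The deposited values are on a log2 scale. The authors made them with MAS5, per the submitters' processing notes, which give no version, and further steps are not given in the sources used here. MAS5 combines the perfect-match and mismatch probes of a probe set into a signal and scales each array as a whole. From the values, the 2% trimmed mean of the unlogged signal was 498.8 on the salinity array and 498.5 on the mock array, so the arrays had been brought to a common level. On the salinity array 2917 values, and on the mock array 2874, are listed at 0. MAS5 signals of dim probe sets vary more than those of bright ones. The SD of the log2 ratio was 0.683 in the dimmest and 0.573 in the brightest of 3 equal groups of probe sets above the bound on both arrays.

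The table held 61035 probe sets. Of these, 37593 have soybean IDs, and 15820 and 7530 have IDs for Phytophthora sojae and soybean cyst nematode, organisms that the array carries beside soybean. The background bound of an array was the 95th percentile of the probe sets of these other organisms, a log2 signal of 4.88 (salinity) and 4.94 (mock). Signals below the bound were raised to it, and a probe set above it on 1 array gives a ratio that is a lower limit ("at least"). The ratio is log2(salinity / mock) of the values as deposited, with no further normalization. Above the bound were 87.8% of soybean probe sets on the salinity array and 87.5% on the mock array. The number of arrays limits the precision.

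Gene names came from a table of the platform's annotation and, through the gene identifier, from the RefSeq gene table of assembly Glycine_max_v4.0, used for names alone. A single gene was given for 8677 probe sets, several for 370, which were left unnamed, and 28546 soybean probe sets are unnamed here. The 8677 probe sets stand for 6031 genes, of which 6010 were found in the RefSeq table, 5892 were measured and 959 of those carry a symbol other than a locus number. The probe set with the highest mean signal stood for a gene. No genome coordinates are given, since the sources name no build for the probe sets.

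With 1 array per group there is no test, and a fixed rule of at least 2-fold was used. A gene list was described by the median log2 ratio of its members above the bound on at least 1 array and by the percentile of that median among 10000 random lists of the same size, matched on mean signal in 10 bins. A list stood apart when that median lay outside the middle 95% of the random medians. For lists of at least 6 genes the 95% binomial interval of the median over its genes was taken from order statistics. Lists of under 5 measured genes got no percentile. The rules on size, background, lists, named genes and alternatives were written before the data were examined. The lists had been defined by words in gene descriptions, which the gene tables used here do not hold. By symbol, 6 of those 36 lists reached 5 genes and 16 found none. The 37 lists used were therefore written from the symbols and synonyms, after the table of values had been opened and before any gene's ratio was computed. Of these, 21 keep the name of a planned list and 16 do not. Among the ranked lists, 7 of 19 with a planned name stood apart. The planned lists for, among others, abscisic acid, ethylene, proton pumps, bHLH factors, cell cycle and root markers could not be formed.

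Named genes were the 12 highest and 12 lowest genes above the bound on both arrays whose probe sets pointed the same way, up to 5 per direction above it on 1 array, up to 2 per direction of each list that differed at least 2-fold (otherwise the member with the largest ratio), and the sodium exchanger gene. That rule asked for a gene description. In its place a symbol other than a locus number was required, a change made after the values had been opened and not written down before ratios were computed. The rule's fallback for missing descriptions, the 2 highest and 2 lowest probe set IDs, is given too. It named 98 genes. Other members of a list are named where their values show its range, as chosen after their values were seen.

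Alternatives were other scalings (median centring, quantile normalization, loess), bounds at the 90th and 99th percentile, log2(signal + 16) with no floor, leaving out probe sets with suffixes for cross-hybridisation, the mean over a gene's probe sets, genes above the bound on both arrays, sizes of 1.5-fold and 3-fold, and counts of genes. The procedure was tested on simulated data made from the mock array with noise of SD 0.3 on the log2 ratio and 33066 measured probe sets. The 2-fold rule recovered 21 of 50 probe sets changed 2-fold, 48 of 50 changed 4-fold, 49 of 50 changed 8-fold and 48 of 50 changed 16-fold, and took up 24 of 32868 unchanged ones. Of 40 unchanged lists of 20 genes, 3 stood apart. The simulated noise was set by hand near the spread between probe sets of a gene, and leaves out noise between arrays and plants. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.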

Results

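Gene expression was compared between salt-treated and mock-treated seedlings of soybean (Glycine max, cultivar Williams 82) on 2 Affymetrix Soybean Genome Arrays. The seedlings were 14 days old when 150 mM NaCl, or water alone, was applied, and RNA from several times up to 24 h was combined into a salinity pool and a mock pool. The labels do not say which organs were taken. Each pool was hybridised to 1 array, so the comparison has no replicates, no test was possible, and the differences below describe these 2 arrays. Of 37593 soybean probe sets, 33784 gave a signal above the background bound on at least 1 array and 32113 on both. The bound was a log2 signal of 4.88 on the salinity array and 4.94 on the mock array.

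The comparison asks which transcripts differed in level between the salt-treated and the mock-treated pool. The highest ratios among named genes belonged to late embryogenesis abundant (LEA) and seed maturation genes, whose products accumulate in drying seeds and in water-stressed tissue. PM9 was 40.8-fold higher on the salinity array, PM41 18.7-fold and LEA5 16.0-fold. Genes for heat shock proteins, glutathione S-transferases and phenylpropanoid and isoflavonoid synthesis were also higher as groups. Of the 41 phenylpropanoid and isoflavonoid genes, 30 lay above 0, with 8 at least 2-fold higher and 5 at least 2-fold lower. Photosynthesis and phloem forisome genes were lower as groups. Gibberellin-response genes had a low median but went both ways, with 13 of 20 below 0 and GASA6, of the gibberellin-stimulated family, 6.43-fold lower. Nitrogen assimilation genes also had a low median and went both ways, and did not stand apart when probe sets marked for possible cross-hybridisation were left out.

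At a rule of at least 2-fold, 1462 probe sets (4.33% of those measured) were higher on the salinity array and 1811 (5.36%) were lower. The balance turned with the size of the difference. At 3-fold or more, 583 probe sets were higher and 500 lower, and at 8-fold or more, 87 were higher and 33 lower. Counted as genes, 296 of 5892 were at least 2-fold higher and 334 at least 2-fold lower. The log2 ratios of probe sets above the bound on both arrays had a median of -0.0029 and an SD of 0.634. As the only repeat measurement available, probe sets of the same gene were compared. The difference in log2 ratio between the brightest and the second brightest set was taken for 1618 genes. Its SD, divided by the square root of 2, was 0.295. That spread covers probe effects and no difference between plants, pools or arrays. Among the 76 genes at least 2-fold higher by their brightest probe set, the second set was higher for 75. It was at least 2-fold higher for 63 of them. Among the 64 at least 2-fold lower, the second set was lower for 60, and at least 2-fold lower for 42.

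**Figure D1:**
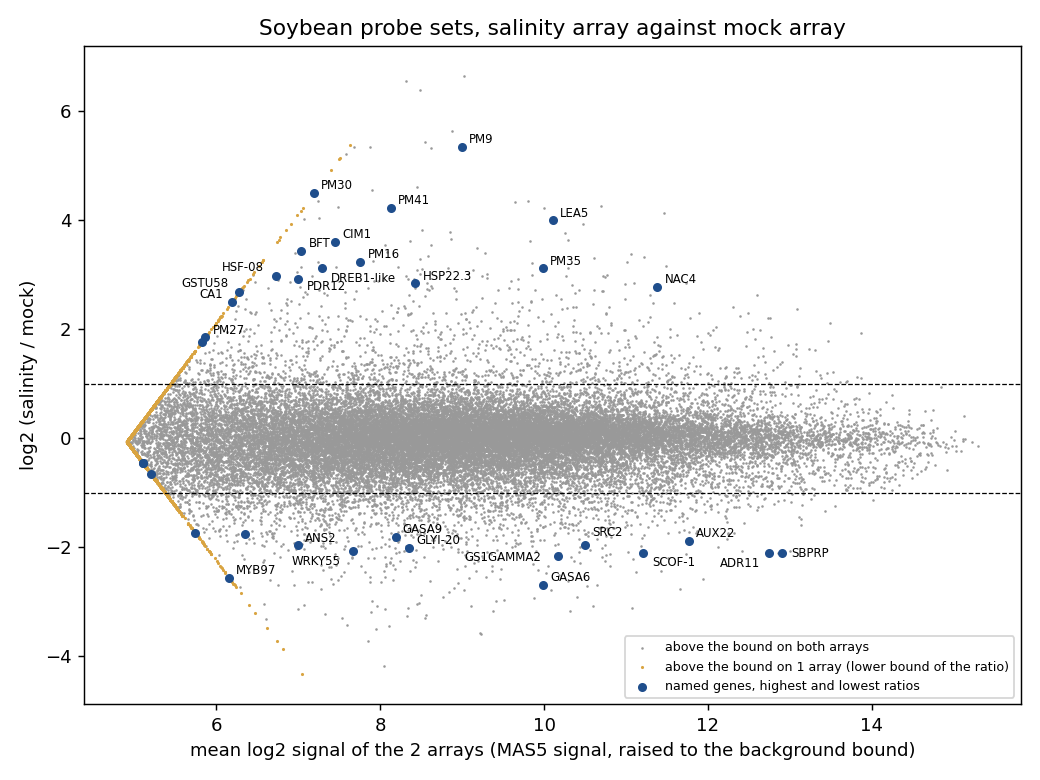
Log2 ratio of the salinity to the mock array (y axis) against the mean log2 MAS5 signal of both arrays (x axis) for the 33784 measured soybean probe sets, with 1 array per group. Grey points were above the bound on both arrays, yellow points on 1 array, where the ratio is a lower limit, dashed lines mark 2-fold, and blue points are named genes, from PM9 at 5.35 to GASA6 at -2.69.

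Beyond PM9, PM41 and LEA5, the highest ratios among genes with a symbol other than a locus number and above the bound on both arrays were those of CIM1 (12.1-fold), a cytokinin-induced gene, BFT (10.9-fold), a relative of the flowering regulators FT and TFL1, and the seed maturation gene PM16 (9.41-fold). They were followed by a DREB1-like factor (8.77-fold), PM35 (8.70-fold), the heat shock factor HSF-08 (7.84-fold), the ABC transporter gene PDR12 (7.56-fold), HSP22.3 (7.17-fold) and NAC4 (6.89-fold). On the mock array, CIM1 (5.65), BFT (5.32), DREB1-like (5.72), HSF-08 (5.24) and PDR12 (5.54) had log2 signals near the bound of 4.94. Their folds and order are therefore less certain. Other probe sets of the same gene gave lower log2 ratios for PM16 (1.88 against 3.23, the higher from a set marked for possible cross-hybridisation), PDR12 (down to 1.79 against 2.92) and HSF-08 (2.38 against 2.97). The lowest ratios after GASA6 under the same limits were those of GS1GAMMA2 (4.45-fold lower), a cytosolic glutamine synthetase gene, the cold-inducible zinc finger gene SCOF-1 (4.32-fold), the proline-rich protein gene SBPRP (4.32-fold) and the auxin-repressed ADR11 (4.29-fold). WRKY55 was 4.19-fold lower, GLYI-20 4.02-fold, ANS2 3.90-fold, SRC2 3.87-fold, the auxin-induced AUX22 3.68-fold, GASA9 3.51-fold and ENOD55-2 3.40-fold. RAV, 3.79-fold lower by its brightest probe set, is left out of this order because its probe sets pointed both ways. Among genes above the bound on the salinity array alone, PM30 was at least 22.7-fold higher, GSTU58 at least 6.42-fold, CA1 at least 5.66-fold, PM27 at least 3.62-fold and PM34 at least 3.40-fold. The PM30 value came from a probe set whose suffix marks possible cross-hybridisation, and the set without that mark gave a log2 ratio of 0.47. Above the bound on the mock array alone, MYB97 was at least 5.89-fold lower, FCL2 at least 3.32-fold, SEOS at least 1.57-fold, LAR1 at least 1.38-fold and BZIP9 at least 1.37-fold. Whatever their gene, the highest probe sets above the bound on both arrays were 100.5-fold and 94.5-fold higher, the first assigned to several genes and the second to LOC100777055. The lowest were 18.0-fold lower (LOC100820426) and 13.2-fold lower (no gene assigned).

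Of 37 gene lists, 35 had at least 5 measured genes and were ranked against 10000 random lists of equal size and like signal. The medians of 13 lists stood apart, that is, outside the middle 95% of the random medians, 9 higher and 4 lower. For independent lists of unrelated genes, chance alone gives 1.75. Genes of a family can move together, and some lists share members, such as CYP93A1, so chance can give more here. Across a list's genes, the 95% binomial interval of the median, which holds no array or plant error, excluded 0 for 6 of the 13, LEA (0.55 to 2.15), heat shock (0.25 to 1.70), glutathione S-transferases (0.28 to 0.87), phenylpropanoid (0.23 to 0.82), photosynthesis (-0.70 to -0.22) and phloem genes (-1.42 to -0.18). It spanned 0 for the other 7, NAC (-0.06 to 0.90), bZIP (-0.05 to 0.32), osmolyte (-0.31 to 1.73), defence (-0.38 to 1.11), sugar (-0.02 to 0.50), gibberellin (-0.90 to 0.13) and nitrogen genes (-0.91 to 0.18). The LEA and seed maturation list had the highest median, a log2 ratio of 1.34, above all its random lists. Of its 32 measured genes, 17 were at least 2-fold higher, none was 2-fold lower, and 29 lay above 0. LEA5 had a log2 signal of 12.11 on the salinity array and 8.11 on the mock array, and PM9 11.67 and 6.32. PM37 (log2 ratio 0.24), ERD15 (0.19) and LEA-2 (0.18) were bright on both arrays and differed little, and PM40 was at -0.40. TENA_E and PARP3 belong to the list through older seed maturation names. The median was 1.90 over the 21 members above the bound on both arrays, and 0.95 without probe sets marked for cross-hybridisation.

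**Figure D2:**
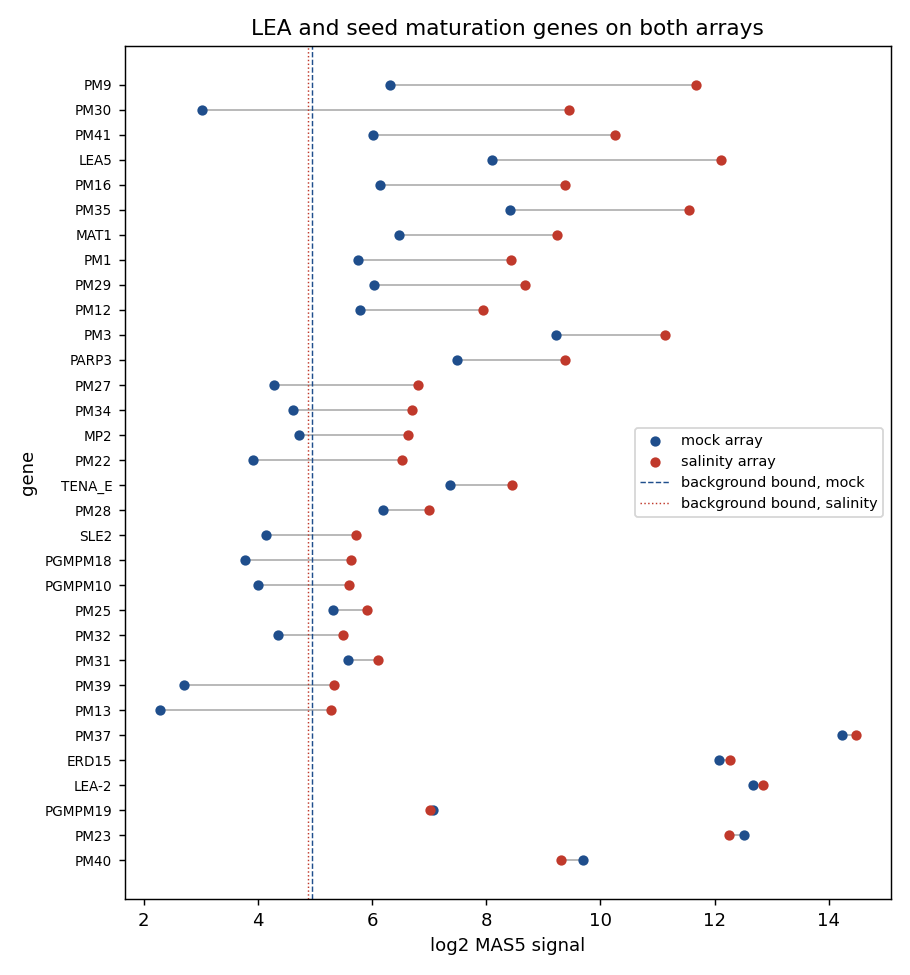
Log2 MAS5 signal (x axis) of the 32 measured LEA and seed maturation genes (y axis) on the mock array (blue) and the salinity array (red), with 1 array per group and vertical lines at each array's background bound. Genes are ordered by the ratio of signals raised to the bound, from PM9 at the top, with 11.67 against 6.32, to PM40, the lowest at -0.40.

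Heat shock proteins and factors had a median log2 ratio of 0.77, above all random lists. Of 17 genes, 6 were at least 2-fold higher and none 2-fold lower, with HSF-08 and HSP22.3 at the top and HSP90-1 near 0. Among transcription factors, the NAC list stood apart at a median of 0.33 (99.9th percentile), with 4 of 20 genes at least 2-fold higher and none 2-fold lower. Its highest values, NAC4 and NAC27 (6.18-fold), came from probe sets of the same transcript cluster and cannot be separated. The bZIP list, which includes factors that bind abscisic acid response elements, had a small median shift of 0.19 (99.9th percentile). Of its 65 genes, 6 were at least 2-fold higher, led by BZIP71 (4.20-fold) and BZIP69 (2.77-fold), and 2 were lower, BZIP50 (2.66-fold) and bZIP84 (2.44-fold). AP2/ERF factors had a median of 0.25 (97.2nd percentile), just inside the limit. They included DREB1-like and DREB2A2 (2.27-fold higher) and, lower, ERF6 (2.04-fold), and they stood apart under 5 of 10 other settings. RAV, of the same list, was 3.79-fold lower by its brightest probe set, but another set gave a log2 ratio of 1.92 in the opposite direction. WRKY factors (median -0.02, 40.5th percentile) and MYB factors (median -0.04, 24.7th percentile) did not stand apart. Within the 53 WRKY genes, 5 were at least 2-fold lower, WRKY55 and WRKY46 (2.76-fold) the most, and 1 was higher. Within the 65 MYB genes, 5 were higher, among them MYB124 (5.71-fold) and MYB184 (4.67-fold), and 3 were lower, among them MYB172 (3.08-fold, with another set at a log2 ratio of -0.93) and MYB186 (2.15-fold).

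Glutathione S-transferases, which conjugate glutathione to reactive compounds, had a median of 0.40, above all random lists. Of 37 genes, 11 were at least 2-fold higher, with GSTU18 (7.69-fold) and GSTU43 (4.89-fold) the highest of those above the bound on both arrays, and 2 were lower, GSTF7 (2.97-fold) and GSTU5 (2.64-fold). Other antioxidant enzymes did not stand apart (median 0.08, 79.7th percentile, 19 genes). AOX1, the gene of a mitochondrial alternative oxidase, was 6.76-fold higher and the ferritin gene SFERH-4 2.49-fold higher. SODB, of the superoxide dismutases, was just over 2-fold lower by its brightest probe set, and its other set gave a log2 ratio of 0.19. Without probe sets marked for cross-hybridisation the antioxidant list stood apart (median 0.19, 97.7th percentile). Class III peroxidases did not (median 0.17, 86.8th percentile), and Ep, of that list, was 2.19-fold lower. Osmolyte metabolism genes had a median of 0.45 (99.6th percentile) over 7 genes. MIPS4, for myo-inositol phosphate synthase, was 3.31-fold higher and GOLS, for galactinol synthase, 2.84-fold higher. The only MIPS4 probe set here is marked for possible cross-hybridisation. For ion transport, only NHX1 and CLC1 were measured. NHX1, a vacuolar sodium/proton exchanger gene, had a log2 ratio of 0.43, and CLC1, a chloride channel gene, was 2.07-fold higher, and each had a probe set pointing the other way. Polyamine genes had a median of 0.11 (72.7th percentile), with the ornithine decarboxylase gene ODC1 2.01-fold lower.

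Phenylpropanoid and isoflavonoid genes had a median of 0.50, above all random lists, with 8 of 41 at least 2-fold higher and 5 lower. CYP93A1, a pterocarpan hydroxylase gene of phytoalexin synthesis, was 5.32-fold higher and the chalcone reductase gene CHR5 3.88-fold higher. ANS2 and DFR2 (3.28-fold), for the anthocyanin enzymes anthocyanidin synthase and dihydroflavonol reductase, were lower. For CYP93A1 the log2 ratio was 2.41, and 1.08 without probe sets marked for cross-hybridisation. The only CHR5 probe set here carries that mark. Defence genes had a median of 0.36 (99.98th percentile), with 7 of 20 at least 2-fold higher. The pathogenesis-related genes PR1-7 (4.92-fold) and PR1-1 (3.11-fold) led, and NDR1b (2.86-fold) and HS1pro1 (2.63-fold) were lower. With the mean over a gene's probe sets, the defence median was 0.17 and no longer stood apart (96.1st percentile). Cytochrome P450 genes did not stand apart (median 0.04, 70.5th percentile), though 7 of 31 were at least 2-fold higher, CYP82A4 (6.53-fold) and CYP93A1 among them. The only CYP82A4 probe set here is marked for possible cross-hybridisation. CYP93A3 (2.89-fold) and CYP82C1 (2.28-fold) were lower. The sugar list had a median of 0.24 (97.9th percentile), with the sucrose transporter gene SUT1 5.52-fold and SWEET29 2.27-fold higher, and lay inside the limit under quantile normalization (97.0th), loess (97.4th) and the mean over probe sets (97.0th).

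The gibberellin list had a median of -0.61, below all its random lists. Of 20 genes, 4 were at least 2-fold lower and 13 lay below 0, with GASA6 and GASA9 the lowest. GA2OX8, for a gibberellin-inactivating oxidase, was 4.20-fold higher, with its other probe set at a log2 ratio of 0.74, and GASA4 2.28-fold higher. Nitrogen assimilation genes had a median of -0.49 (0.065th percentile), with GS1GAMMA2 and the nitrate reductase gene INR1 (2.38-fold) lower, and ALAAT1 (2.18-fold) and GS1alpha (2.08-fold) higher. Without probe sets marked for cross-hybridisation that median was -0.15 (14.3rd percentile) and did not stand apart. The only INR1 probe set here carries that mark. Photosynthesis and chlorophyll synthesis genes had a median of -0.46 (0.18th percentile). Of 15, 13 lay below 0, but FTRC alone, for a ferredoxin-thioredoxin reductase subunit, was at least 2-fold lower (2.11-fold). All 8 measured phloem genes for forisome and sieve element occlusion proteins lay below 0 (median -0.67, 0.40th percentile), SEOA 2.67-fold. Fatty acid genes had a median of -0.25 (3.04th percentile), just inside the limit, and stood apart under 5 of 9 other settings. The desaturase genes FAD3C (3.26-fold) and FAD6.1 (2.29-fold) were lower and SACPD-C 2.38-fold higher.

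**Figure D3:**
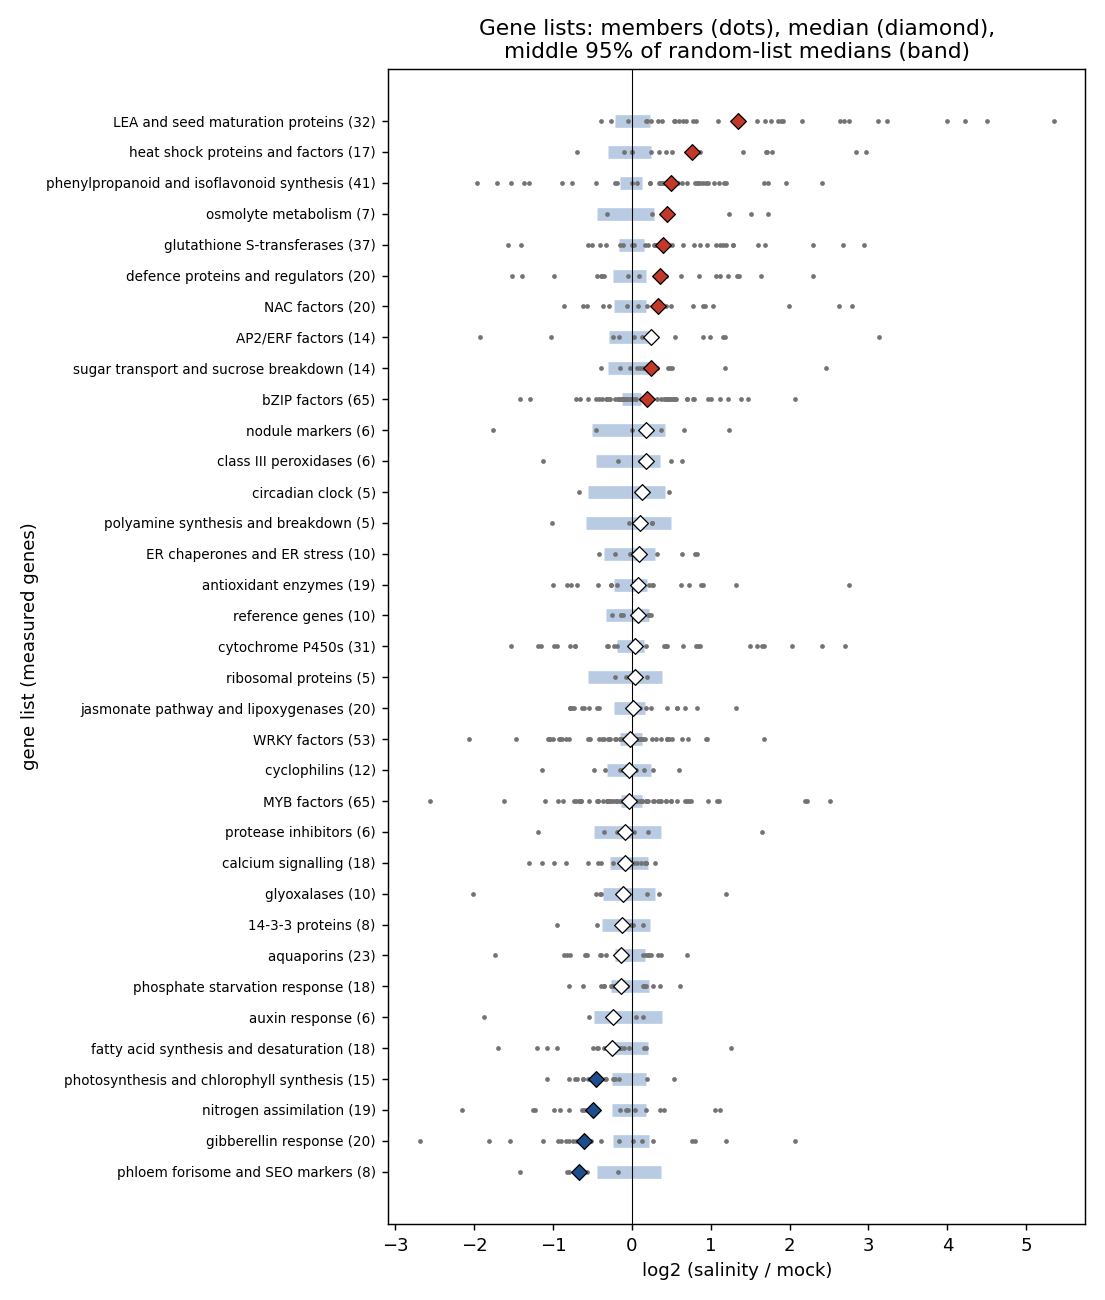
Log2 ratio of the salinity to the mock array (x axis) for the 35 ranked gene lists (y axis, measured genes in parentheses), with dots for genes, diamonds for medians and bands for the middle 95% of medians of 10000 random lists. Red diamonds mark the 9 lists that stood apart as higher, with LEA genes at 1.34, blue the 4 as lower, with phloem genes at -0.67, and white the others, where AP2/ERF and fatty acid genes lie near the limit.

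The other functional lists did not stand apart. The median was -0.09 for calcium signalling (23.3rd percentile), where SCA1 was 2.47-fold lower. It was 0.09 for the list of endoplasmic reticulum chaperones and endoplasmic reticulum stress genes (73.5th percentile), where NRP-B was 1.77-fold higher. Aquaporins lay at -0.14 (9.42nd percentile), with PIP2-1 3.34-fold lower by its brightest set and at a log2 ratio of -0.07 by its other. ANN11, of the calcium list, was 2.21-fold lower by a set marked for cross-hybridisation, and another of its sets gave a log2 ratio of -0.10. The jasmonate list lay at 0.01 (59.5th percentile), with LOX10 2.49-fold higher, but at -0.34 (0.815th percentile) without probe sets marked for cross-hybridisation. Auxin genes lay at -0.23 (15.2nd percentile), with AUX22 the lowest, protease inhibitors at -0.08 (35.9th percentile), with BBI-1 3.12-fold higher (log2 ratio 1.64, and 1.09 by its unmarked set) and BBI-2 2.28-fold lower, and circadian clock genes at 0.13 (73.7th percentile), with MYB114 1.59-fold lower. The phosphate starvation list lay at -0.14 (12.1st percentile), with SPX3 1.74-fold lower, and glyoxalases at -0.12 (23.9th percentile), with GLYI-20 lower and GLYI-6 2.28-fold higher. Cyclophilins lay at -0.04 (43.5th percentile), with CYP53 2.20-fold lower, and 14-3-3 proteins at -0.12 (24.8th percentile), with SGF14n 1.93-fold lower. Ribosomal protein genes lay at 0.03 (62.4th percentile), with RPS6 at -0.21 and its probe sets pointing both ways. The control list of reference genes had a median of 0.08 (81.1st percentile), and none of its 10 genes, SUBI-1 (-0.25, probe sets pointing both ways) included, differed 2-fold.

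Markers of other tissues and a sign of RNA makeup were measured beside these groups. Of 12 seed storage genes, 3 were above the bound on the salinity array, and the brightest, BG7S-1, had a log2 signal of 6.22 there and 5.66 on the mock array. Of 18 nodule genes, 6 were measured (median 0.18, 82.9th percentile), with N-36A 2.34-fold higher and ENOD55-2 lower. The only N-36A probe set here is marked for possible cross-hybridisation. Probe sets for soybean ribosomal RNA were brighter on the salinity array. Of the 42 above the bound on at least 1 array, 38 were higher there and 18 at least 2-fold higher, with a median log2 ratio of 0.85. That shift lay on the same single pair of arrays as the differences between gene groups, so whether it is linked to any of them cannot be told.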

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

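All tests in this part were chosen after the ribosomal RNA values were seen. Probe sets for soybean ribosomal RNA lie outside the main comparison, and their signal on the salinity array was above that in the mock control. The median log2 ratio was 0.85 over the 42 probe sets above the bound on at least 1 array, with 38 higher on the salinity array. Among the 24 probe sets whose IDs carry no RC mark, 18 were measured with a median of 1.31, and among the 24 with that mark the median was 0.52.

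The median over the 32113 soybean probe sets above the bound on both arrays was -0.0029, so no overall offset was left in the values. Since the arrays had been brought to a common level beforehand, that median had little room to differ from 0. It is no independent test of scaling. The ribosomal median was 0.85 under median centring, and 0.86 under quantile normalization and under loess. Noise of dim probe sets is argued against as the whole cause. The 35 ribosomal probe sets above the bound on both arrays had a median of 0.85 (0.8526), above all random lists of soybean probe sets of like signal. All of them target ribosomal RNA and may move together, unlike the random lists, so that rank and the count of 38 do not rest on independent members. The shift was smaller in the probe sets with the RC mark, which were brighter. They had a median log2 signal of 10.44 on the mock array, and 21 of 24 were higher, with a median ratio of 0.52. All 24 without the mark had a median mock signal of 4.85, and the 18 measured ones had a median ratio of 1.31. Of these, the 11 above the bound on both arrays were all higher, with a median of 1.40. Mark and signal went together, so the smaller shift cannot be assigned to signal. More ribosomal or degraded RNA in the labelled salinity target may account for the shift, but with 0 control probe sets for labelling and RNA quality in the table used here, and 1 array per group, it cannot be told apart from an effect of salt. The salt treatment itself stays open as an untested explanation.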

How the results depend on the processing

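Each group has 1 array, so no array could be left out. No paired analysis was possible because each group has 1 array and no test was made. Scaling to hybridisation controls was not run, as the table used here holds 0 of them. Counts of probe sets stayed within 1.5 times under the other scalings, bounds, floor and probe set filter. At 1.5-fold, 8619 probe sets differed (3790 higher, 4829 lower), at 3-fold 1083 (583 higher, 500 lower), and counted as genes 630 (296 higher, 334 lower), against 3273 (1462 higher, 1811 lower). These shifts follow from the rule and from the smaller number of genes. The share of higher among differing probe sets was 44.7%, and 45.1%, 47.0% and 47.7% under median centring, quantile normalization and loess.

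Of 339 recomputed list medians, 335 stayed within the allowed range and 4, all of lists of under 6 genes, moved. That range was the binomial interval of the main median or, under 6 genes, 0.295 over the square root of their number. The intervals are wide, so staying inside them is a weak check. The jasmonate median moved from 0.01 to -0.34 without marked probe sets and stood apart there, yet stayed inside its interval (-0.61 to 0.45). No median of a list that stood apart changed sign. The seed storage median (0.11) was 0.51 with the 99th percentile bound, 0.44 with no floor and 0.55 over genes above the bound on both arrays, where fewer genes remain. The ion transport median (0.74) was 0.49 with the mean over probe sets. The LEA, heat shock, glutathione S-transferase, phenylpropanoid, osmolyte, NAC, bZIP, gibberellin, photosynthesis and phloem lists stood apart under every setting run. Under the planned word lists, applied to symbols as chosen after seeing the data, AP2/ERF factors stood apart (0.41, 99.5th percentile). Of 775 recomputed values of named genes, 721 moved by less than 0.295, 52 by more, and 2 changed sign: without probe sets marked for cross-hybridisation RAV was at 1.92 and SODB at 0.19, both because another probe set then stands for the gene. Signal over background limits genes read on 1 array, whose ratios follow the bound.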

Other observations

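The phenylpropanoid list held a split that the comparison of the whole list does not show. Branch membership was set from textbook pathways after the values had been seen, and of the tests in this part, those on related transcripts were written before their results and the others after. For the split, the ratios of all members, and that of CYP93A1 without marked probe sets, had been seen by then. Of 14 measured genes of the isoflavonoid branch, which leads to the phytoalexins of legumes, 13 were higher on the salinity array, 5 of them at least 2-fold (median log2 ratio 0.81, 95% binomial interval over genes 0.23 to 1.73). They included CHR5, the isoflavone reductase gene IFR (log2 ratio 1.73), the isoflavone synthase gene IFS2 (1.19) and G4DT (1.10), a prenyltransferase gene of glyceollin synthesis. Of 7 measured genes of the flavonol and anthocyanin branch, 6 were lower, 3 at least 2-fold (median -0.88, interval -1.96 to 0.39, which spans 0), including ANS2 (-1.96), DFR2 (-1.71), UGT78K1 (-1.31), FLS1 (-0.88) and F3H (-0.76).

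The difference of branch medians was 1.69. For signal shared between related transcripts, probe sets marked for cross-hybridisation were left out, which lowered CYP93A1 from 2.41 to 1.08 and left 11 and 7 genes. The medians were then 0.80 and -0.98 and the difference 1.78. That was past the bound of 0.89 written before this result, 3 times the SD between probe sets of 1 gene. A 95% interval from resampling genes, added after the difference was known, was 0.99 to 2.66. Since the branches were drawn after the ratios were seen and most members stayed, a fall below the bound was unlikely from the start. The interval takes the branches as given and does not allow for that choice. The values show only that the split remained among genes read by unmarked probe sets, and the test cannot decide on a cause. Unmarked probe sets were not tested for shared signal. Noise of dim probe sets may still account for part of the split, since among genes brighter than the median gene, where the difference was 1.63, only 2 genes of the flavonol and anthocyanin branch remain. No biological explanation was tested, nor a difference between the pools other than salt.

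The higher LEA and seed maturation genes were weighed in the same way. Seed tissue in the salinity pool is argued against as the whole cause, by a limit written after the values were seen. Of 12 seed storage genes, among the most abundant seed transcripts, 3 were above the bound on the salinity array. The median log2 signal of the 12 was 4.10 there and 3.45 on the mock array. It was thus higher on the salinity array, but under the bound on both. Noise of dim probe sets is argued against by the median of 1.90 over the 21 members above the bound on both arrays, above all random lists. Signal shared between related transcripts could add to the size of the shift, since without marked probe sets the median was 0.95, above all random lists but under the log2 ratio of 1 set in advance. With 1 array per group, a difference between the pools other than salt cannot be told apart from salt.

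RAV was the single gene, of 1618 with several probe sets above the bound on both arrays, whose sets differed at least 2-fold in opposite directions. Its probe sets gave log2 ratios of -1.92, 1.92 and -0.76.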
